A study of Mus musculus with 6 samples.

How the data were processed

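CUT&Tag with an antibody against NUP214 was carried out on sorted mouse bone marrow cells, per the labels' protocols. Hematopoietic stem cells (HSCs) were CD48-CD150+LSK cells of Nup214fl/+ mice. Leukemia stem cells (LSCs) were lineage-negative cells of mice with MLL-AF9 leukemia, gated as Sca-1 negative and positive for c-Kit, CD34 and CD16/32, either Nup214fl/+ (control LSCs) or Nup214fl/+,Tie2-Cre (Nup214-HET LSCs). Each of the 3 groups had 2 libraries, numbered 1 and 2 in the sample titles, from which the groups were taken.

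The submitters' processing notes name FastQC 0.11.5, Bowtie2 2.2.9, MACS2 and ChIPseeker, with no version for the last pair, and the mm10 build. The authors called peaks separately in each library, per the file layout, so replicates could be compared. The treatment of duplicate reads, a control sample and the MACS2 settings are not given in the sources used here. For each peak the authors' deposited lists give a fold enrichment (a linear ratio of the summit over the local background), a −log10 p and a −log10 q, and a score, which is the whole part of 10 times the −log10 q in nearly all lines. The deposited −log10 q values start at 1.30 to 1.32 in every list, so the lists end at a q of 0.05. The lists hold no read totals. Read alignment, duplicates and fragment length therefore act on every number below through the peak lists alone.

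An implied depth was computed from the authors' fold and −log10 p columns. MACS2's formula for the fold (summit pileup plus 1, over background plus 1) and its Poisson p give the summit pileup as a whole number, which was recovered within a relative tolerance of 0.0001 for 97.6% to 99.95% of the peaks of a list. The formula comes from the tool and the values, not from the labels. The lowest background in a list was taken as the genome-wide background pileup: 0.374 and 0.0991 in control LSCs, 0.393 and 0.392 in Nup214-HET LSCs, and 0.697 and 0.310 in HSCs. The smallest peak width stood for the fragment length used by the caller: 145 and 143 bp, 320 and 329 bp, and 205 and 229 bp in the same order. Background over this width is the implied depth, which orders libraries only as far as these assumptions hold. The smallest summit pileups were 4, 3, 4, 4, 6 and 5, so the lower limit of a called peak lay at 10.7, 30.3, 10.2, 10.2, 8.61 and 16.1 times the background. The largest fold of a list may be limited by the fragment length, so folds were used only to describe and rank peaks within a list.

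Peaks on chromosomes 1 to 19, X and Y were kept. Peaks were taken as overlapping with at least 1 bp in common. A consensus region of a group is a merged region overlapped by peaks of both its libraries. Regions called in all 6 libraries were merged into 109 common regions of 123.7 kb in all. Genes came from a RefSeq table of GRCm38.p6, the same build as mm10, with 21887 protein-coding genes. The table gives no strand. Peaks within 1 kb of a transcription start, as planned, were therefore replaced by peaks within 1 kb of either annotated end of a protein-coding gene, called gene-end peaks. Only the outermost ends were searched, so a transcription start farther than 1 kb inside a gene was missed. Exons, introns and UTRs were not told apart. A gene belonged to a group's set when both libraries had a gene-end peak. Of the names in the gene lists, Nup58 and Nup42 were matched through Nupl1 and Nupl2, and Fsp1 and Ahsp were not matched. The motif test needs the genome sequence and was not run.

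Groups were compared by exact permutation tests of the values per library (two-sided, smallest p 0.33 with 2 against 2), gene sets by Fisher's exact test over all protein-coding genes, and gene lists by Fisher's exact test with Benjamini-Hochberg adjustment at 0.05. The 15 lists covered ferroptosis suppressors and drivers, MLL-fusion targets, HSC identity, granulocyte-monocyte progenitor, nucleoporin, p53 target, cell cycle, ribosomal protein, erythroid, megakaryocyte, B cell, T and NK cell, and endothelial and stromal genes, with olfactory receptors as the negative control. Peak strength was compared by a permutation test with 100000 resamples of the median fold percentile. Shares of 1 library have Wilson 95% intervals, which cover counting error only. The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes, from each class of genes (control LSC set with no gene-end peak in the other group, both sets, other set with none in control LSCs), the 10 with the highest mean percentile of fold in the libraries that define the class, leaving out symbols that start with Gm or end in Rik. It adds every member of the ferroptosis, MLL-fusion target, HSC identity and granulocyte-monocyte lists in at least 1 group's set, and Nup214. One gene that the rule takes is not reported here.

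Alternatives were a −log10 q of at least 2.64 (2 times the largest minimum of the lists), lists cut to the strongest 634 peaks by q, each library left out, an overlap of 50% of the shorter peak, a window of 3 kb, a peak in either library, all sequences, and a replicate block. Limits of 50 times the background, with and without scaling by the smallest peak width, lists without the common regions and whole gene spans were added after the data were seen. The width-scaled limit was added last, since a longer fragment raises the background pileup and so lowers the ratio at narrow sites. The code was tested on simulated data first: lists were called in 0.286%, 17.0%, 87.7% and 99.3% of cases at odds ratios of 1, 2, 4 and 8 for the control LSC gene set, and 100% of 3000 simulated pileups were recovered. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.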

Results

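NUP214, a protein of the nuclear pore complex, was mapped on mouse chromatin by CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA beside its target. The 6 libraries came from bone marrow and fell into 3 groups of 2. None is labelled as a control without the NUP214 antibody, so transposase cutting unrelated to NUP214 was not measured. Control leukemia stem cells (LSCs) were sorted from Nup214fl/+ mice with acute myeloid leukemia driven by MLL-AF9, a fusion oncogene. Nup214-HET LSCs came from such mice that also carried Tie2-Cre, a recombinase active in blood and endothelial cells. Normal hematopoietic stem cells (HSCs) came from Nup214fl/+ mice. The labels' cell type entry reads as hematopoietic stem cell for all 6 libraries, so the groups follow the sample titles. No label says that the libraries of a group came from separate animals, so the p-values of comparisons between groups of libraries measure only the spread between these libraries, which may be technical. Those of Fisher's exact tests run over genes and those of peak strength over peaks, which are not replicates. The deposited data are peak lists, 1 per library, on the mm10 build. Read totals were not given in the sources used here. An implied depth was recovered from each list, and it was 3.72 times as high in control LSC library 1 as in library 2. Relative to that same library 2 it was 1.77 and 1.72 in the Nup214-HET LSC libraries and 4.90 and 1.95 in the HSC libraries.

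The Nup214 gene itself (chromosome 2, 31974408 to 32053975) had a peak at 31974196 to 31974616, over 1 end of the gene, in control LSC library 1, with a fold enrichment of 13.3. None of the other 5 lists held a peak at either end of Nup214. A peak at the gene does not measure its dose or its expression, so the genotype labels were not checked by these data.

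NUP214 peaks were most numerous in control LSCs, fewer in Nup214-HET LSCs and fewest in HSCs. Control LSC libraries 1 and 2 held 25437 and 10525 peaks, and the Nup214-HET LSC libraries held 5452 and 4681. The HSC libraries held 1045 and 634. The peaks covered 8376 and 2690 kb in control LSCs, 2744 and 2419 kb in Nup214-HET LSCs, and 399 and 250 kb in HSCs. On the log2 scale the control LSC mean lay 1.70 above that of Nup214-HET LSCs, a 3.24-fold difference, and 4.33 above that of HSCs, a 20.1-fold difference. In peak number both control LSC libraries exceeded every library of the other groups, while in covered length control LSC library 2 lay below Nup214-HET library 1. The exact permutation test (two-sided, n = 2 per group) gave p = 0.33 for each comparison, which is the smallest p that 2 against 2 libraries allow. Peak numbers depend on depth, and control LSC library 2, with the lowest implied depth of the 6, still held 1.93 times as many peaks as the longer Nup214-HET list. Among peaks whose summit reached at least 50 times the library's own background, a limit chosen after the data were seen, the control LSC libraries held 8297 and 7678, the Nup214-HET libraries 955 and 762, and the HSC libraries 107 and 121. With the limit scaled for peak width, the Nup214-HET libraries held 3083 and 2610 such peaks and the fold between the LSC groups was 2.81 in place of 9.36. Between control LSCs and HSCs it was 43.9 in place of 70.1. Neither form of the limit is free of depth: the smallest summits lay at 30.3 times the background in control LSC library 2, against 10.7 in control LSC library 1 and 10.2 in both Nup214-HET libraries.

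**Figure D1:**
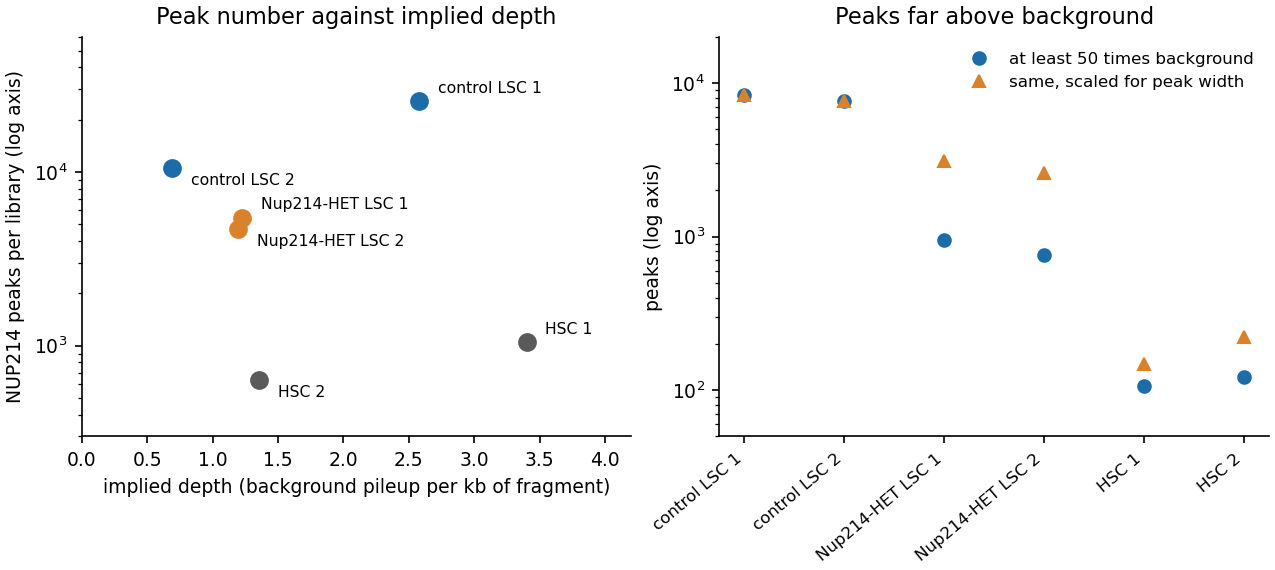
Left, number of NUP214 peaks per library on a log axis against the implied depth, in background pileup per kb of fragment, with 1 point per library. Right, peaks per library, on a log axis, whose summit reached at least 50 times the library's background, as counted (circles) and scaled for peak width (triangles). Control LSC library 2 has the lowest implied depth and 10525 peaks, above both Nup214-HET libraries and both HSC libraries.

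The same called regions recurred between libraries of a group to differing degrees. Of the shorter list, 64.2% of the control LSC peaks overlapped a peak of the other library by at least 1 bp. The values were 39.9% for Nup214-HET LSCs and 35.5% for HSCs. These values depended on the setting: with lists of equal length the 3 groups had 71.0%, 69.6% and 33.1%, and at 50 times the background the 3 groups had 65.2%, 81.6% and 82.2%, or 65.2%, 63.4% and 85.8% when scaled for peak width. Regions called in both libraries numbered 6668 in control LSCs, 1867 in Nup214-HET LSCs and 219 in HSCs. A set of 109 regions was called in all 6 libraries and took 0.491% and 1.24% of the control LSC peaks, 2.04% and 2.37% of the Nup214-HET peaks, and 11.3% and 18.1% of the HSC peaks. The region on chromosome 2 from 98666240 to 98667333 had the highest −log10 q in each of the 6 lists. No list of regions prone to artifacts was applied here, so signal unrelated to NUP214 was not told apart at the common regions. Of the 219 HSC regions, 50.7% overlapped these common regions, and without them the HSC overlap was 21.2%.

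**Figure D2:**
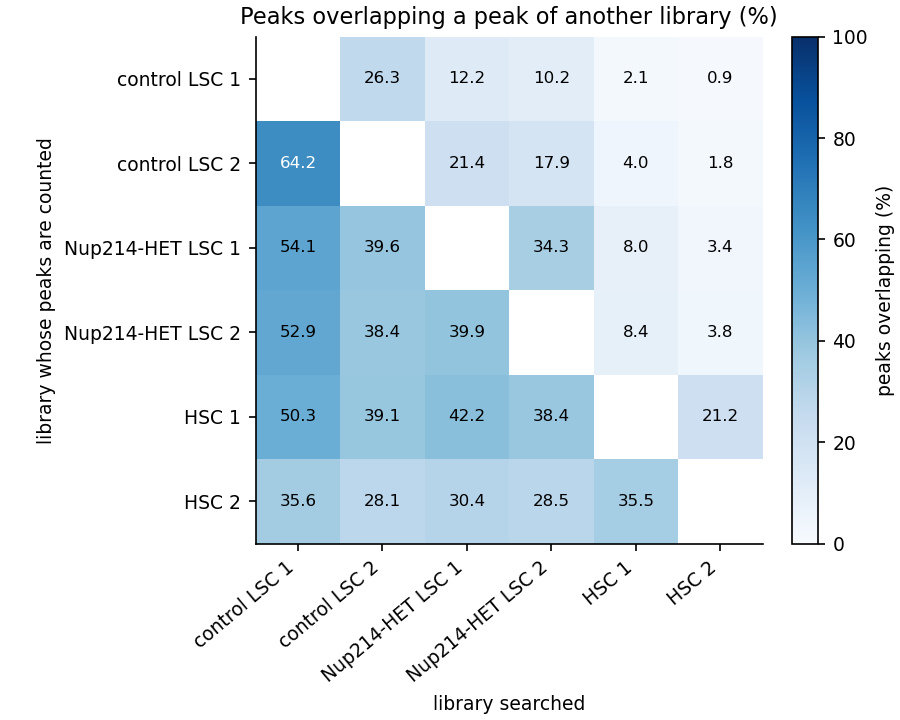
Percent of the peaks of each library (rows) that overlap a peak of another library (columns) by at least 1 bp, with the diagonal left blank. Of the peaks of control LSC library 2, 64.2% overlap library 1, and 35.5% of the peaks of HSC library 2 overlap HSC library 1.

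NUP214 peaks of both LSC groups lay near the ends of protein-coding genes far more often than the genome offers such sequence. Those of HSC library 1 did so less often than in LSCs, and the share in HSC library 2 was near that of the genome. Within 1 kb of an annotated gene end lay 35.3% (Wilson 95% interval 34.8 to 35.9) and 39.4% (38.5 to 40.4) of the control LSC peaks. The share was 37.5% (36.2 to 38.8) and 35.4% (34.1 to 36.8) in Nup214-HET LSCs. It was 17.3% (15.1 to 19.7) in HSC library 1 and 3.00% (1.93 to 4.63) in HSC library 2. These windows made up 2.91% of the chromosomes. Peaks shifted by 50 kb met them in 7.60% and 6.94% for control LSCs, 7.41% and 7.33% for Nup214-HET LSCs, and 4.02% and 4.10% for HSCs. Genes with a gene-end peak numbered 9485 and 4800 in control LSCs, 2524 and 2076 in Nup214-HET LSCs, and 227 and 19 in HSCs, of 21887 protein-coding genes. The mean share was 37.4% ± 2.90 (SD, n = 2) in control LSCs, 36.4% ± 1.45 (SD, n = 2) in Nup214-HET LSCs and 10.2% ± 10.1 (SD, n = 2) in HSCs. The LSC groups differed by 0.949 percentage points, less than the spread between replicates, with p = 1 (exact permutation test, two-sided). This difference turned to −12.1 points among peaks of at least 50 times the background, to −0.828 with that limit scaled for peak width, and to −5.34 with a stricter q. Control LSCs exceeded HSCs by 27.2 points (exact permutation p = 0.33, the smallest possible). The annotation used here gives no strand, so the start and the end of a gene were not told apart, and intervals cover counting error only. Without a control library, gene-end peaks were not told apart from transposase cutting unrelated to NUP214.

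**Figure D3:**
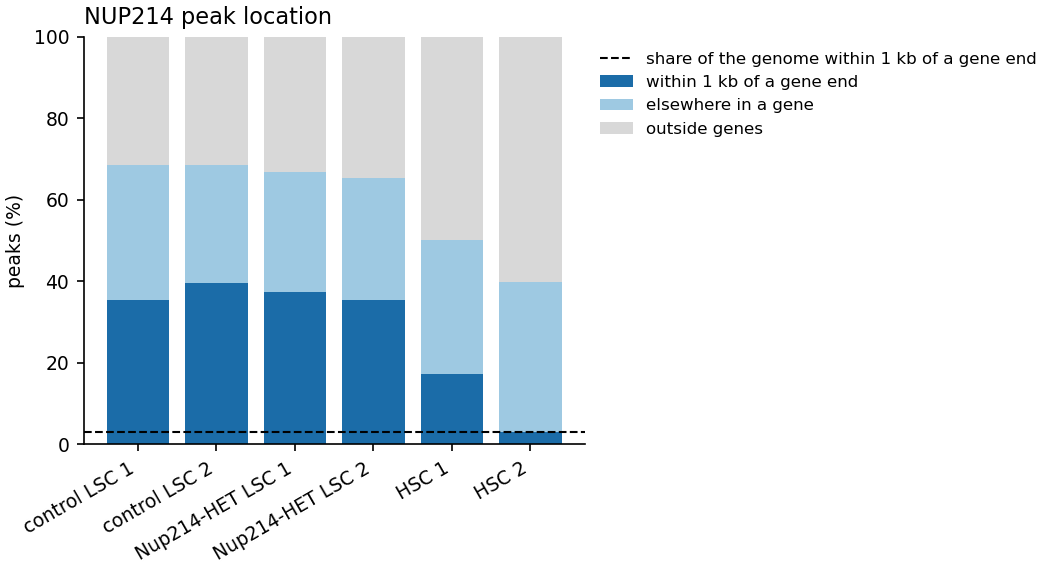
Percent of NUP214 peaks per library within 1 kb of an end of a protein-coding gene, elsewhere in a gene, or outside genes (stacked bars), with the share of the chromosomes within 1 kb of a gene end as a dashed line at 2.91%. The LSC libraries lie between 35.3% and 39.4% near gene ends, and HSC library 2 lies at 3.00%.

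The genotype comparison asked which NUP214 sites of control LSCs were also called in Nup214-HET LSCs. In lists as deposited, most control LSC regions had no peak there, while most Nup214-HET regions had a peak in control LSCs. With lists cut to the same length the shares were alike, at 56.3% and 57.6%. Such shares depend on list length, so the difference between the directions does not by itself show lost sites. Of the 6668 control LSC regions, 32.0% and 26.7% overlapped a peak in the 2 Nup214-HET libraries, a mean of 29.4% ± 3.76 (SD, n = 2), against 0.450% and 0.480% after a shift of 50 kb. Both Nup214-HET libraries had 1389 of them (20.8%), and neither had 4138 (62.1%). Regions near a gene end were called in both Nup214-HET libraries in 25.5% of cases, and other regions in 14.2%. In the reverse direction, 83.4% ± 11.2 (SD, n = 2) of the 1867 Nup214-HET regions overlapped a control LSC peak, with 91.3% and 75.4% in the 2 libraries. The percentages rest on requiring both libraries of a group: with control LSC library 1 or library 2 left out, the share kept in Nup214-HET LSCs was 19.6% or 11.2%. With Nup214-HET library 1 or library 2 left out, the reverse share was 45.6% or 46.9%.

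Among genes, Tle4, a transcriptional corepressor, Eif4ebp2, a translation repressor, Sf1, a splicing factor, and Ep400, a chromatin remodeler, had gene-end peaks in all 4 LSC libraries. Camsap1, Tmem123, Eloa, Ankrd50, Phlpp1, Gpbp1, Pwwp3a, Tada1, Clic4 and Impdh2 had the strongest control LSC gene-end peaks among genes with no gene-end peak in either Nup214-HET library. Phlpp1 had 1 peak within its span in Nup214-HET library 1. The peak at Camsap1, which encodes a microtubule-binding protein, lay on chromosome 2 from 25983273 to 25983776 in control LSC library 1, with a fold enrichment of 22.4, and had 17.7 in library 2. That at Tmem123 lay on chromosome 9 from 7763670 to 7764228, with folds of 18.1 and 20.6. Eloa, which encodes an elongin subunit, had folds of 24.3 and 15.5, with a peak on chromosome 4 from 136021666 to 136021994. The Tle4 peak on chromosome 19 (14598047 to 14598790) had folds of 20.1 and 14.4 in control LSCs and 11.0 and 11.3 in Nup214-HET LSCs. Csnk1g2, Tmem80, Vkorc1l1, Lars2 and the neighbours Ap2a1 and Tsks, which share 1 peak, completed the strongest genes of both LSC groups, and the Lars2 peak belongs to the regions called in all 6 libraries. These folds are the authors' values per peak and rank peaks only within a list.

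Genes with a gene-end peak in both libraries numbered 4655 in control LSCs and 1480 in Nup214-HET LSCs. The sets shared 1273 genes where independent sets of these sizes would share 314.8 (odds ratio 31.0, Fisher's exact test, p too small to be represented). Of the control LSC genes, 2362 (50.7%) had no gene-end peak in either Nup214-HET library and 1020 had one in a single library. Only 17 genes of the Nup214-HET set had no gene-end peak in either control LSC library. By strength they were led by Cflar, a regulator of apoptosis, on chromosome 1 from 58711934 to 58712766 with folds of 7.51 and 9.27. Next came Mcemp1, Apoc2, Tmprss9, Abraxas2, Ints6l, Trnau1ap, the neighbours S100a1 and S100a13, and Duxf3. Control LSC libraries 1 and 2 still held 1 and 2 peaks within the span of Cflar. They held 1 and 1 within Ints6l, 1 and 1 within Trnau1ap, and 1 and 0 within Tmprss9. The other named genes had none there. Without control LSC library 2, the genes with no gene-end peak in Nup214-HET LSCs numbered 6515, and without Nup214-HET library 2 the shared genes numbered 1960. Cut to the shortest list, 194 genes were shared and 129 had no gene-end peak in Nup214-HET LSCs.

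Control LSC regions called in both Nup214-HET libraries ranked higher in their own lists than those called in neither. The median percentile of fold enrichment was 90.3 against 77.9 in control LSC library 1 and 83.3 against 54.8 in library 2. The differences of 12.4 and 28.6 had a permutation p of 1e-05, the smallest that 100000 resamples can give, with peaks not being independent replicates. With lists cut to the same length the difference was −25.6 in library 1 (permutation p = 1e-05) and 1.18 in library 2 (permutation p = 0.812).

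Control LSCs and HSCs of the same Nup214fl/+ genotype were compared to ask which NUP214 sites leukemia stem cells and normal stem cells have in common. Few control LSC genes had a gene-end peak in HSCs. The control LSC genes with the strongest gene-end peaks and no gene-end peak in HSCs were the neighbours Adam9 and Tm2d2 on chromosome 8, with 1 peak from 25016640 to 25017339 and folds of 21.1 and 20.4, followed by Cbwd1, Cdv3, Rxylt1, Tmem123, the neighbours Foxred1 and Srpr, Ntmt1 and Eloa. Of the 6668 control LSC regions, 5.67% and 2.47% overlapped an HSC peak, a mean of 4.07% ± 2.26 (SD, n = 2), and 6277 (94.1%) overlapped none. Without control LSC library 2 the mean was 1.52%, and with lists cut to the same length it was 23.3%. Of the 219 HSC regions, 85.4% and 70.3% overlapped a control LSC peak, a mean of 77.9% ± 10.7 (SD, n = 2). Leaving out HSC library 1 gave 31.9%, leaving out HSC library 2 gave 44.7%, and lists cut to the same length gave 35.7%. Of the 219 HSC regions, 50.7% overlapped the regions called in all 6 libraries, each of which holds a control LSC peak by definition. Without those regions the share seen in control LSCs was lower than 77.9%.

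The HSC set held 9 genes with a gene-end peak in both libraries, and 7 of them were in the control LSC set where 1.91 would be shared by independent sets (odds ratio 13.0, Fisher's exact p = 0.000468). They were Wls, a carrier of Wnt proteins, Lars2, Lypd4, Ppm1b, Zbtb20, Rab40c and Sp1. All but Wls overlapped a region called in all 6 libraries, and without those regions 1 gene was shared. Wls had folds of 32.3 and 10.6 in control LSCs and 25.0 and 25.1 in HSCs, at a peak on chromosome 3 starting at 159939405. These folds rank peaks only within a list. No gene of the HSC set lacked a gene-end peak in both control LSC libraries, and 4448 control LSC genes (95.6%) had no gene-end peak in HSCs. The HSC libraries differed: of the 227 genes of HSC library 1, 203 (89.4%) were in the control LSC set where 48.3 would be shared (odds ratio 32.7, Fisher's exact p = 6.58e-109). Of the 19 genes of HSC library 2, 11 were in it where 4.04 would be (odds ratio 5.10, Fisher's exact p = 0.00054).

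The study's title names ferroptosis, an iron-dependent form of cell death, so ferroptosis genes were among the 15 lists fixed before the data were examined. Ribosomal protein, nucleoporin and cell cycle genes had gene-end peaks in control LSCs more often than other genes, and olfactory receptor genes, the negative control, less often. By Fisher's exact test, the ribosomal protein list had 20 of 33 genes in the control LSC set (odds ratio 5.72, adjusted p = 8.05e-06), the nucleoporin list 17 of 31 (4.51, adjusted p = 0.000215) and the cell cycle list 15 of 30 (3.71, adjusted p = 0.00174). Of the olfactory receptor genes, 0 of 1110 were in it (Fisher's exact test, adjusted p = 4.40e-118), against 22.4% of other genes. The adjustment was that of Benjamini and Hochberg over the 15 lists. Leaving out 1 library at a time gave odds ratios from 5.50 to 9.51 for ribosomal protein, 4.33 to 8.85 for nucleoporin and 3.57 to 11.8 for cell cycle genes, the highest in each case without control LSC library 2. Cut to the length of the shortest list, 0 lists lay above the other genes, and the ribosomal protein odds ratio was 0. So short a cut leaves few genes in the control LSC set, so the test could then miss enrichment in lists of these sizes. All protein-coding genes served as the background, which includes genes silent in these cells, and expression was not used here. Transposase cutting unrelated to NUP214 was not measured. In simulated lists of these sizes the test called 87.7% of lists at an odds ratio of 4 and 17.0% at 2.

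Neither ferroptosis list passed the test in control LSCs. Of the ferroptosis suppressors, 10 of 29 were in the control LSC set (odds ratio 1.95, Fisher's exact test, adjusted p = 0.147), against 21.3% of other genes. Ftl1, a ferritin chain, Slc3a2, a subunit of the cystine transporter, Nfe2l2 and Atf4, both transcription factors of stress responses, and Vkorc1l1 were in both LSC sets. Scd2 had a gene-end peak in 1 Nup214-HET library. Dhodh, Gss, Nfs1 and Nqo1 had no gene-end peak in either, although Nfs1 had 1 peak within its span in Nup214-HET library 1. The Slc3a2 peak on chromosome 19 from 8722886 to 8723514 had folds of 15.2 and 8.66 in control LSCs and 7.83 and 4.28 in Nup214-HET LSCs. The Ftl1 peak on chromosome 7 from 45459619 to 45460117 had folds of 9.17 and 7.18, then 4.73 and 5.64. Folds rank peaks only within a list, so they do not compare the groups. Starts farther than 1 kb inside a gene were not searched, so a gene without a gene-end peak may have a peak at a start. Of the suppressors with no gene-end peak in any library, 4 had a peak within their span. Control LSC libraries 1 and 2 held 2 and 1 peaks within Gpx4, which reduces lipid peroxides, and library 1 held 3 within Slc7a11, the other subunit of the cystine transporter, and 2 within Txnrd1, with no such peak in the other libraries. Fth1, a ferritin chain, had 1 in each of the 4 LSC libraries and none in HSCs. These 4 genes lie outside the rule for named genes and were chosen after their values were seen. Of the ferroptosis drivers, 12 of 33 were in the control LSC set (odds ratio 2.12, Fisher's exact test, adjusted p = 0.113). Cyb5r1 and Vdac2 were in both LSC sets. Tfrc, the transferrin receptor, Aco1 and Lpcat3 had a gene-end peak in 1 Nup214-HET library, and Bach1, Far1, Ireb2, Map1lc3a, Pcbp2, Ptgs2 and Slc39a14 had no gene-end peak in either. Of these 7, Ireb2 had 2 peaks within its span in Nup214-HET library 2 and Slc39a14 had 1 in library 1. Ncoa4, which carries ferritin to autophagy, was in the Nup214-HET set and also had a gene-end peak in control LSC library 1, with a fold of 11.8. Without control LSC library 2 both lists passed, with adjusted p = 0.0428 for the suppressors and 2.73e-05 for the drivers (Fisher's exact test). In the same exact test, a window of 3 kb took the suppressors past the threshold (adjusted p = 0.0242), and so did accepting a peak in either library (0.0448), which also took the drivers past it (3.36e-05).

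**Figure D4:**
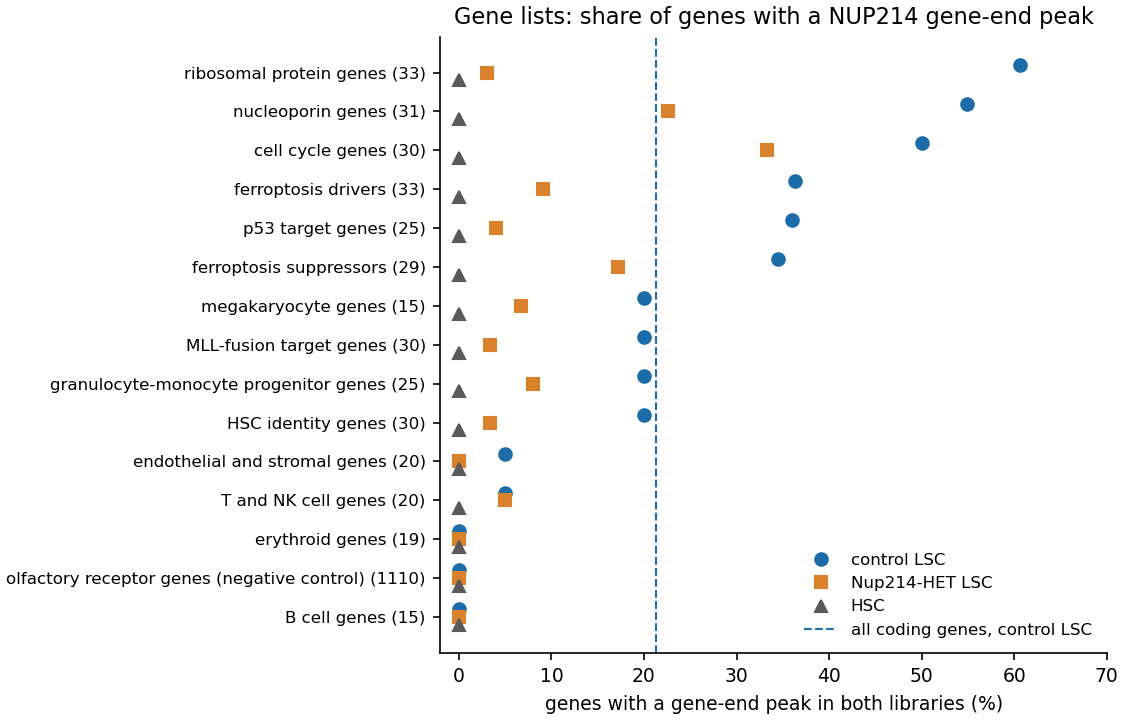
Percent of the genes of each fixed list, with the number of genes in parentheses, that had a gene-end peak in both libraries of control LSCs (circles), Nup214-HET LSCs (squares) and HSCs (triangles). The dashed line marks all protein-coding genes in control LSCs. Ribosomal protein genes stand at 60.6% in control LSCs and 3.03% in Nup214-HET LSCs, and every list stands at 0% in HSCs.

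MLL-fusion target, HSC identity and granulocyte-monocyte progenitor genes did not pass the test in control LSCs (odds ratio 0.925 and adjusted p = 1 for each, Fisher's exact test). The odds ratio lay above 1 without control LSC library 2 for the MLL-fusion targets (1.96) and the granulocyte-monocyte genes (1.42), and without control LSC library 1 for the HSC identity genes (1.29). Of the 30 MLL-fusion targets, 6 were in the control LSC set. Myc, Runx1, Sox4, Tcf4 and Arid1b had no gene-end peak in Nup214-HET LSCs, and Cbx8 had one in 1 Nup214-HET library. Within their spans, Runx1 and Arid1b each had 1 peak in each Nup214-HET library. Pbx3 was in the Nup214-HET set and also had a gene-end peak in control LSC library 1, with a fold of 7.48. The Myc peak on chromosome 15 from 61984979 to 61985701 had folds of 6.49 and 4.99. HSC identity genes also counted 6 of 30. Among them, Egr1 was in both LSC sets and Lyl1 had a gene-end peak in 1 Nup214-HET library. Ctnnal1, Msi2 and Runx1 had no gene-end peak in either. Within its span, Msi2 had 1 peak in Nup214-HET library 2, and Runx1 had 1 in each. Of 25 granulocyte-monocyte progenitor genes, 5 were in the set. Csf2ra, a receptor chain for GM-CSF, was in both LSC sets, while Cebpa, Csf2rb, Ctsc and Mpo, which encodes myeloperoxidase, had no gene-end peak in Nup214-HET LSCs. Spi1 was in the Nup214-HET set and also had a gene-end peak in control LSC library 1, with a fold of 5.80. The p53 targets counted 9 of 25 (Fisher's exact test, adjusted p = 0.147), and passed without control LSC library 2 (adjusted p = 0.000839) or with either library (0.000912). Markers of other cell types did not pass the exact test: 0 of 19 erythroid genes (adjusted p = 0.0621), 3 of 15 megakaryocyte genes (1), 0 of 15 B cell genes (0.113), 1 of 20 T and NK cell genes (0.147) and 1 of 20 endothelial and stromal genes (0.147). The endothelial and stromal list passed the exact test, below other genes, without control LSC library 2 (adjusted p = 0.00515) and with either library (0.00506).

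Gene-end peaks of 5 ferroptosis suppressors and 2 ferroptosis drivers were kept in both Nup214-HET libraries, and no list passed a test of losing its peaks more or less often than the other control LSC genes. Of the 12 lists with a gene in the control LSC set, 0 passed Fisher's exact test after adjustment and 0 had an unadjusted p under 0.05, the lowest being 0.203 for cell cycle genes. The lowest adjusted p was 0.930. Lists with few control LSC genes could hardly pass at any outcome, such as the granulocyte-monocyte progenitor list with 5 and the T and NK cell list with 1. For such lists the test could not tell even from uneven loss, and the simulation did not cover it. Of the suppressors 4 of 10 had no gene-end peak in either Nup214-HET library (odds ratio 0.647), and of the drivers 7 of 12 (1.36). The counts were 5 of 6 for MLL-fusion targets (4.86), 4 of 5 for granulocyte-monocyte progenitor genes (3.89) and 8 of 20 for ribosomal protein genes (0.646). Without Nup214-HET library 1 the ribosomal protein odds ratio turned to 4.76 and that of the granulocyte-monocyte genes was 2.11, and without control LSC library 2 that of the MLL-fusion targets was 1.60.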

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

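The tests in this part were all chosen after the results were seen. Peaks on sequences other than chromosomes 1 to 19, X and Y stayed outside the comparisons and numbered 52 and 42 in the control LSC libraries, 30 and 30 in the Nup214-HET LSC libraries, and 50 and 30 in the HSC libraries. They drew attention because the main comparisons did not use them.

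Nup214-HET LSCs had fewer NUP214 peaks than control LSCs. Lower depth alone is argued against, as far as the implied depth holds. Relative to control LSC library 2 it was 1.77 and 1.72 in the Nup214-HET libraries, and 3.72 in control LSC library 1. Library 2 still held 10525 peaks, against 5452 and 4681. Among peaks at least 50 times above each library's own background, scaled for peak width, control LSC libraries held 2.81 times as many. Each exceeded both Nup214-HET libraries. That limit is not free of depth: the smallest summits lay at 30.3 times the background in control LSC library 2 and 10.2 in Nup214-HET libraries. Different library preparation cannot be told apart from genotype, because the smallest peak widths of the LSC groups were separated by a gap of 175 bp and each group had its own width. The reduced Nup214 gene dose in the design stays open as an untested biological explanation.

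HSC lists held few gene-end peaks. Lower depth is argued against, as far as the implied depth holds. Relative to control LSC library 2 it was 4.90 and 1.95 in HSCs, and 3.72 in control LSC library 1. Gene-end peaks numbered 181 and 19 in HSCs, against 4152 in control LSC library 2. Those at least 50 times above background, scaled for width, numbered only 9 and 6 in HSCs and were 581.5 times as many per library in control LSCs. Both control LSC libraries exceeded both HSC libraries in them, though that limit is not free of depth. For the lists as called, a make-up of regions called in every library is argued against too, since such regions took at most 18.1% of an HSC list. For the 219 regions called in both HSC libraries it is not argued against, since 50.7% of them overlapped such regions. A weak antibody signal in the HSC libraries cannot be told apart from little NUP214 at gene ends, because either would lower the share of gene-end peaks, which without the common regions was 2.50% in HSC library 2, near the 2.91% of the chromosomes, and 18.9% in HSC library 1, above it. Different library preparation cannot be told apart from cell type either. The smallest peak widths were 205 and 229 bp in HSCs and 145 and 143 bp in control LSCs. The difference between normal and leukemia stem cells stays open as an untested biological explanation.

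Folds at the strongest regions were lower in Nup214-HET LSCs, with a largest fold of 28.2 and 27.2 against 58.8 and 57.5 in control LSCs and 45.4 and 40.8 in HSCs. A ceiling set by fragment length may account for this: the largest folds differed by 2.16 times between libraries, and after multiplication by the smallest peak width by 1.14 times, with each product below 10 kb, a local window MACS2 commonly uses. No biological explanation was tested.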

How the results depend on the processing

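The limits of 50 times the background, the lists without common regions and the whole gene span were chosen after seeing the data, and the other alternatives before. Peak number kept its direction in both comparisons under every alternative run, with p at or above 0.33 by design. No list passed the test of loss from Nup214-HET LSCs under any alternative run, a test that lists with few control LSC genes could hardly pass. The other values below moved, and unless their construction shows the cause (fewer peaks or libraries), the cause was not tested. The motif test was not run, no region had several summits to count separately, and an odds ratio that could not be formed has no value. Sites below a library's limit are not in its list, so a missing peak does not show absent NUP214. No numbers pair the samples: over 34085 merged regions the deviations of same-numbered libraries correlated at −0.0225 (control and Nup214-HET LSCs), −0.0253 (control LSCs and HSCs) and 0.00711 (Nup214-HET LSCs and HSCs). Under the replicate block peak number differed by 1.70 and 4.33 on the log2 scale (exact p = 0.5, the smallest 2 pairs allow). Under the block the share of control LSC peaks kept in Nup214-HET LSCs was 15.0%, of Nup214-HET peaks seen in control LSCs 46.3%, of control LSC peaks seen in HSCs 1.97%, and of HSC peaks seen in control LSCs 39.2%.

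With a stricter q, replicate overlap was 73.7% in control LSCs, 52.8% in Nup214-HET LSCs and 46.2% in HSCs, and the gene-end share of control minus Nup214-HET LSCs was −5.34 points. With equal list length, overlap was 71.0% and 69.6% in the LSC groups. Control LSC regions were kept in Nup214-HET LSCs at 56.3% and seen in HSCs at 23.3%, while Nup214-HET and HSC regions were seen in control LSCs at 57.6% and 35.7%. The LSC sets then shared 194 genes, 129 control LSC genes had no Nup214-HET gene-end peak and 309 no HSC one, 0 lists lay above other genes, and the ribosomal protein odds ratio was 0. With so few genes in the control LSC set, the list test could miss enrichment. The strength difference was −25.6 in control LSC library 1 and 1.18 in library 2. With an overlap of 50%, replicate overlap was 62.3% and 38.4% in the LSC groups. With a window of 3 kb, control LSCs and HSCs shared 12 genes. With either replicate, 10.1% of control LSC peaks were kept in Nup214-HET LSCs and 1.41% seen in HSCs, and 38.3% of Nup214-HET and 34.0% of HSC peaks were seen in control LSCs. Shared genes then numbered 2980 with Nup214-HET LSCs and 221 with HSCs, control LSC genes with none 6650 and 9409, lists above other genes 6 and below 2.

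At 50 times the background, replicate overlap was 65.2%, 81.6% and 82.2% in control LSCs, Nup214-HET LSCs and HSCs, the gene-end difference between LSC groups −12.1 points, the share kept 15.4% and HSC regions seen in control LSCs 95.9%. Shared genes were 518 with Nup214-HET LSCs and 1 with HSCs. Scaled for width, replicate overlap was 65.2%, 63.4% and 85.8%, the gene-end difference −0.828 points and the share kept 33.8%. Without common regions, replicate overlap was 38.5% in Nup214-HET LSCs and 21.2% in HSCs, HSC regions seen in control LSCs 56.5% and genes shared with HSCs 1. Over whole gene spans 65 genes were shared with HSCs.

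Leaving out each library in turn, the gene-end difference between LSC groups ranged from −1.10 to 3.00 points, falling below 0 without control LSC library 2 and, at −0.0769, without Nup214-HET library 2. The share of control LSC peaks kept in Nup214-HET LSCs ranged from 11.2% to 32.0%, and Nup214-HET peaks seen in control LSCs from 45.6% to 91.3%. Control LSC peaks were seen in HSCs at 1.52% to 5.67%, and HSC peaks in control LSCs at 31.9% to 85.4%. Shared genes ranged from 1273 to 1960 with Nup214-HET LSCs and from 7 to 203 with HSCs, and control LSC genes with none from 2362 to 6515 and from 4448 to 9266. Lists above other genes ranged from 3 to 6 and below from 1 to 2. Over all alternatives together, not only those leaving out a library, 278 odds ratios of single lists kept their direction and side of the threshold. Of the rest, 9 came to pass it, 2 no longer passed it and 37 changed direction.

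The 37 that changed direction lay past the threshold under neither setting, apart from the ribosomal protein list at equal length, which passed before. For lists in control LSCs they were, with a stricter q, 1.02 for MLL-fusion targets. At equal length, where the control LSC set held few genes, they were 0 for ferroptosis drivers and p53 targets, 2.25 for granulocyte-monocyte and 3.86 for megakaryocyte genes. With 3 kb they were 1.10, 1.10 and 1.42 for MLL-fusion targets, HSC identity and granulocyte-monocyte genes. With either replicate they were 1.91, 1.27 and 1.38 for the same lists and 1.11 for megakaryocyte genes. At 50 times the background HSC identity genes had 1.16, and over whole gene spans MLL-fusion targets had 1.62, HSC identity genes 2.13 and megakaryocyte genes 1.22. Leaving out each library gave 0.890 to 1.96 for MLL-fusion targets, 0.925 to 1.29 for HSC identity, 0.890 to 1.42 for granulocyte-monocyte and 0.872 to 1.29 for megakaryocyte genes. For lists lost in Nup214-HET LSCs they were, with a stricter q, 0.911 for ferroptosis drivers, 0.912 for megakaryocyte and 1.11 for ribosomal protein genes, and at equal length 0 for granulocyte-monocyte genes. With either replicate T and NK cell genes had 1.12. At 50 times the background HSC identity genes had 0.567, granulocyte-monocyte genes 0.851, cell cycle genes 1.04 and ribosomal protein genes 4.56. Over whole gene spans ferroptosis drivers had 0.732, MLL-fusion targets 0.549, HSC identity genes 0.299, megakaryocyte genes 0.733 and T and NK cell genes 1.10. Leaving out each library gave 0 to 1.14 for T and NK cell genes and 0.369 to 4.76 for ribosomal protein genes.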

Other observations

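Gene families outside the fixed lists, defined by the start of their symbols, were chosen and counted after the data were seen. Of the 21 genes whose symbols start with Hnrn, which encode RNA-binding proteins of pre-mRNA processing, 14 were in the control LSC set (odds ratio 7.42, adjusted p = 1.59e-05, Fisher's exact test with Benjamini-Hochberg adjustment over 10 families), and 11 of these (78.6%) were also in the Nup214-HET set, against 27.3% of all control LSC genes (odds ratio 9.82, adjusted p = 0.000862 over the 9 families with a gene in the control LSC set). Families of translation initiation factors (30 of 56, odds ratio 4.29), RNA polymerase subunits (17 of 29, 5.26), complex I subunits (24 of 49, 3.57), mitochondrial ribosomal proteins (30 of 78, 2.32), proteasome subunits (20 of 51, 2.39) and heat shock proteins (20 of 30, 7.43) also had control LSC peaks more often than other genes, with adjusted p between 2.77e-07 and 0.00322. For none of these 6 families did the share kept in Nup214-HET LSCs pass a test against other control LSC genes (Fisher's exact test, adjusted p = 1 for each, lowest unadjusted p 0.454). Keratin and keratin-associated genes (0 of 112), vomeronasal receptors (1 of 355) and potassium channels (3 of 94) had control LSC peaks less often (adjusted p 1.60e-11, 9.82e-35 and 1.61e-06).

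Ribosomal protein genes, above other genes in control LSCs, were at 1 of 20 kept in both Nup214-HET libraries (Rps19), against 27.3% of all control LSC genes, with an odds ratio of 0.139, an unadjusted p of 0.0223 and an adjusted p of 0.225 over 12 lists (Fisher's exact test, chosen after the data were seen). The Nup214-HET libraries differed here, with gene-end peaks at 13 and 4 of the 33 genes. Cell cycle genes were kept at 8 of 15 (odds ratio 3.05, Fisher's exact test, unadjusted p = 0.0375, adjusted p = 0.225), among them Pcna, Cdc6, Cdt1, Mcm4 and Mcm7, which act in DNA replication.

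Peaks within 1 kb of a tRNA gene's span lay at 127 and 48 of 408 tRNA genes in control LSCs, 30 and 28 in Nup214-HET LSCs, and 3 and 0 in HSCs. Of 63 rRNA genes, 18 and 2 had such a peak in control LSCs, 17 and 17 in Nup214-HET LSCs and 0 in both HSC libraries. Of 39 Hox genes, 3 and 2 had a gene-end peak in control LSCs, 1 in each Nup214-HET library and 0 in both HSC libraries.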
